A study of Mus musculus with 6 samples.

How the data were processed

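Each array held labelled RNA of the ipsilateral cortex of 1 mouse, 3 after tMCAO and 3 after sham surgery, per the labels. RNA was digested with RNase R, then amplified with random priming and labelled with Cy3, per the labels' protocols. The deposited values are spot intensity values on a linear scale from Agilent Feature Extraction 11.0.1.1, background-subtracted and detrended but not scaled between arrays, per the file headers. Other deposited columns used were the spot flags and the array position, per the file headers. The array design names genome build mm9, per the file headers.

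The processed intensity of each spot was taken as log2, spots flagged as non-uniform or population outliers were left out, and spots of 1 probe were averaged, with a median of 7 spots for a circRNA probe. Each array's 75th percentile over circRNA probes was subtracted. The plan named non-control probes for this percentile. It was read as the circRNA probes, because the features typed as non-control also include spike-in, negative and circRNA control features, and the percentile over all of these was run as an alternative. A probe was detected on an array when over 0.5 of its unflagged spots were well above background, and it was tested when detected on at least 3 of the 6 arrays. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment), with group as the sole term. Array-level values were compared by an exact permutation test. Between any pair of arrays 0% of spots held exactly the same processed intensity, and each array was counted as 1 sample.

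The rule for named circRNAs, set before the data were examined, took adjusted calls first, then those with an unadjusted p under 0.05, at least 1.5-fold and no overlap, in order of p. It filled 10 places in each direction, and the first 2 of each are named. Tests of host gene lists, cell type markers, circRNA classes and hosts with several circRNAs were planned and not run, because no table used here pairs circRNA probes with genes. The mRNA probes were named through their accessions and RefSeq genes of assembly GRCm38.p6, which matched 44 of 50. The comparison of mRNA probes, and the choice of those named, came after the data were seen.

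The files used here hold no mean pixel signal, so normexp correction and raw brightness, intended for it, used the median pixel signal, with a normexp offset of 50. All 6 arrays came from 1 scan, so a block for slide or scan was not possible, and array row was used as a block, chosen after the data were seen. The other alternatives were quantile normalization, other scalings, other filters on dim probes, other variance models, array weights, a replicate block, a plain equal-variance test and leaving out each array. Samples sharing a replicate number did not deviate together in every pair, so numbers were not treated as pairing. Weights for the mRNA probes came from the circRNA fit.

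The test was tried on simulated data with the real means and residual spread of 1305 circRNAs, 200 of them changed, in 20 simulations. limma recovered 57.9% of 2-fold and 91.1% of 4-fold changes, and 4.46% of its calls were false. These simulations draw each circRNA independently and hold no shift shared by many circRNAs on 1 array.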

Results

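Circular RNAs, closed loops made by back-splicing of exons, were measured in the cortex on the operated side of adult male C57BL/6J mice after a transient stroke or a sham operation. In the stroke group a filament blocked the middle cerebral artery for 1 h, and tissue was taken after 12 h of reperfusion (transient middle cerebral artery occlusion, tMCAO). The sham group had the surgery with no filament. Each group held 3 mice, and each mouse had its own 1-colour array of 1797 circRNA probes and 50 mRNA probes. RNA was digested with RNase R, an exonuclease that degrades linear RNA, before labelling. The number of arrays limits the precision of every value given here.

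Of the 1797 circRNA probes, 1483 were well above background on at least 1 array, 1307 on at least 3 arrays and 1072 on all 6. The tMCAO arrays detected 1444, 1220 and 1089 circRNA probes, and the sham arrays 1354, 1281 and 1246. The mean was 1251 ± 180 (SD, n = 3) in tMCAO and 1294 ± 55.1 in sham (exact permutation test, two-sided, p = 0.8, where 0.1 is the smallest p that 3 arrays against 3 can give). The 75th percentile of circRNA intensity before scaling was 6.66 ± 0.63 on the log2 scale in tMCAO and 6.92 ± 0.22 in sham (SD, n = 3, exact permutation test, two-sided, p = 0.6). No spot was saturated.

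The comparison of tMCAO with sham asks which circRNAs differ in ischemic cortex. ASCRMP001402 averaged 3.23 ± 0.19 (SD, n = 3) in tMCAO and 1.73 ± 0.62 in sham on the scaled log2 axis, a difference of 1.49 ± 0.32 (SE). ASCRMP000261 averaged 2.09 ± 0.80 in tMCAO and 0.56 ± 0.31 in sham, a difference of 1.53 ± 0.40. In the other direction, ASCRMP001250 averaged -0.998 ± 0.62 in tMCAO and 0.98 ± 1.07 in sham, a difference of -1.97 ± 0.55. ASCRMP000224 averaged -0.73 ± 0.50 in tMCAO and 1.16 ± 1.13 in sham, a difference of -1.89 ± 0.55. For each of these 4 circRNAs the 3 tMCAO values lay apart from the 3 sham values, which the rule for naming them required. Their unadjusted p-values from limma were 0.00193, 0.00554, 0.00771 and 0.00957, and the adjusted p was 0.604 for each. Without sham 1, ASCRMP000224 differed by -1.24 and ASCRMP001250 by -1.36. Over the 23 alternatives ASCRMP000224 ranged from -2.43 to -1.13, ASCRMP001250 from -2.52 to -1.14 and ASCRMP000261 from 1.18 to 1.97. ASCRMP000261 had an adjusted p of 0.023 in limma with array weights, in a range of 0.023 to 0.976. The files used here do not pair circRNA probes with host genes, so these circRNAs are named by probe alone.

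None of the 1307 circRNAs passed an adjusted p of 0.05 in limma with all 6 arrays equally weighted (0 circRNAs). At an unadjusted p under 0.05 there were 92, of which 49 were higher and 43 lower in tMCAO, where chance alone gives 65.4. Of these, 77 differed by at least 1.5-fold, 40 higher and 37 lower. With arrays scaled over probes detected on all 6 arrays the split was 92 higher and 21 lower. Scaling by the median gave 33 and 40, quantile normalization 32 and 29, and scaling to circRNA control probes 30 and 31. With normexp background correction in place of the processed signal, and the same scaling, it was 11 higher and 29 lower. The 2 groups did not overlap for 157 circRNAs, 85 higher and 72 lower, which is 12.0% of those tested where chance gives 10%. Both chance values are averages, and circRNAs move together on an array. Other ways to divide the 6 arrays into 3 and 3 gave 30 to 433 circRNAs without overlap. They gave 5 to 343 with an unadjusted p under 0.05 (limma), so neither 157 nor 92 stands apart. The median log2 difference over all tested circRNAs was 0.03, and scaling over probes detected on all 6 arrays moved it to 0.18.

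**Figure D1:**
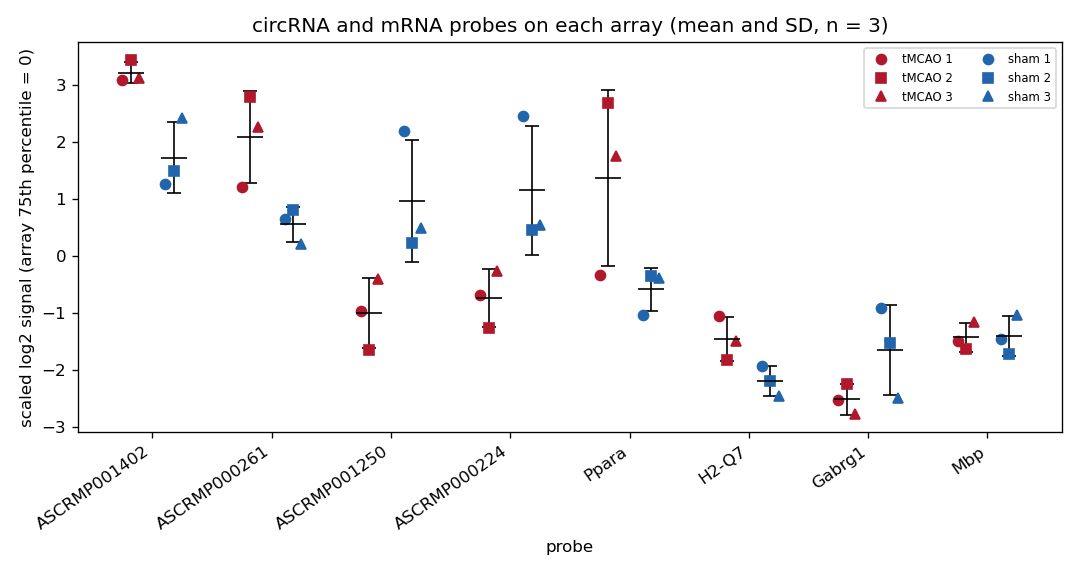
Scaled log2 signal (vertical axis, 0 at each array's 75th percentile) of 4 circRNA and 4 mRNA probes (horizontal axis) on each array, tMCAO in red and sham in blue, with bars for the mean and SD of 3 arrays. ASCRMP001402 lies at 3.10 to 3.44 on the tMCAO arrays and at 1.27 to 2.44 on the sham arrays, while Mbp overlaps between groups.

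Among the fits that left out 1 array, the count of circRNAs past the adjusted threshold was above 0 only without sham 3. With every array kept but weighted, limma gave 223 circRNAs with an adjusted p under 0.05. The weight was lowest for sham 3, at 0.294. The other arrays were weighted unequally too, from 0.498 for tMCAO 1 to 2.98 for sham 2, so that count does not rest on sham 3 alone. Without sham 3, 112 circRNAs had an adjusted p under 0.05 in limma, 29 higher and 83 lower in tMCAO, and 297 met the unadjusted p and 1.5-fold rule. ASCRMP001402 then differed by 1.85 with an adjusted p of 0.0117 from limma, and its adjusted p ranged from 0.0117 to 0.976 over the 23 alternatives. Leaving out sham 1 or sham 2 gave 0 adjusted calls, with 23 and 26 circRNAs under the unadjusted rule. Across the tested circRNAs, sham 3 correlated at r = 0.988 with tMCAO 3 and at 0.971 with tMCAO 1, against 0.927 with sham 1 and 0.941 with sham 2. These are correlations over circRNAs, which are not independent replicates. Sham 1 and sham 2 correlated at 0.988 with each other. Sham 3 and tMCAO 3 shared array row 2, and the other 4 arrays lay in row 1. With row as a block, 0 circRNAs had an adjusted p under 0.05 and 117 met the unadjusted rule. Within row 1, with 2 arrays per group, the counts were 0 and 275, and row 2 held 1 array per group and gave no test.

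**Figure D2:**
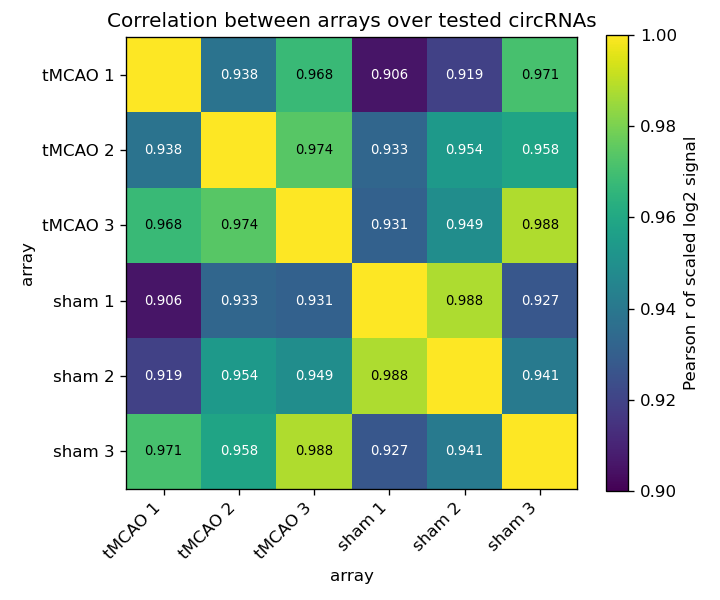
Pearson correlation of scaled log2 signal between each pair of arrays (both axes) over the tested circRNAs, coloured from 0.9 to 1. Sham 3 has its highest value, 0.988, with tMCAO 3, and its value with sham 1 is 0.927.

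**Figure D3:**
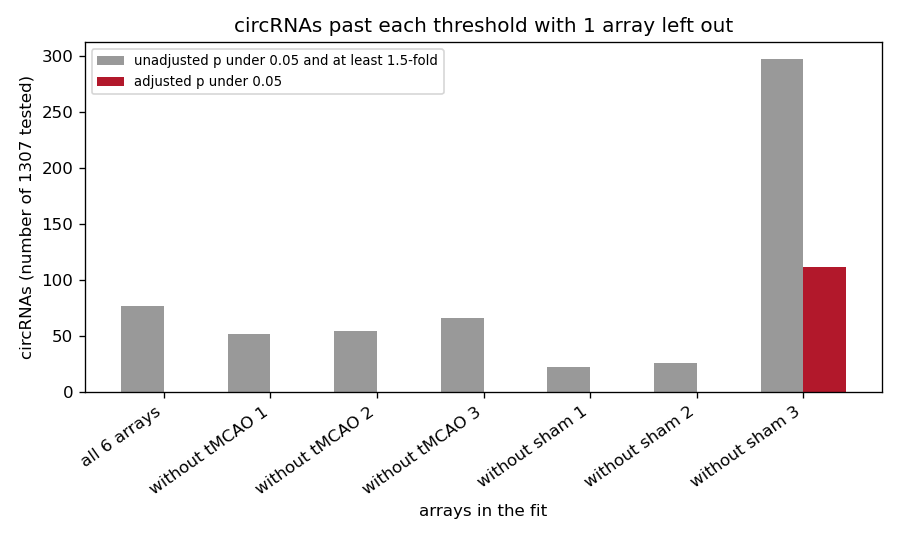
Number of circRNAs past each threshold (vertical axis, of 1307 tested) with all 6 arrays and with each array left out (horizontal axis), in grey for an unadjusted p under 0.05 with at least 1.5-fold and in red for an adjusted p under 0.05. The red bar is above 0 only without sham 3, at 112.

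Of the 50 mRNA probes, 29 were tested, and the comparison of these named genes was chosen after the data were seen. RNase R digestion came before labelling, so signal at an mRNA probe comes from what digestion left and is not a measure of expression. How far digestion sets the differences below was not tested. Ppara, a nuclear receptor that regulates fatty acid oxidation, averaged 1.37 ± 1.55 (SD, n = 3) in tMCAO and -0.58 ± 0.38 in sham, a difference of 1.95 ± 0.65 (SE). H2-Q7, a nonclassical MHC class I gene, differed by 0.75 ± 0.36. tMCAO 1 was at the sham level for Ppara, at -0.335 against -0.339 on sham 2, and the difference was carried by tMCAO 2 and tMCAO 3, at 2.69 and 1.75. It was 1.29 without tMCAO 2 and 2.80 without tMCAO 1. After scaling, H2-Q7 had all 3 tMCAO values above all 3 sham values. Before scaling the groups overlapped, at 6.32, 4.62 and 4.69 (log2) on the tMCAO arrays and 5.16, 4.81 and 4.21 on the sham arrays. Rps4l, a ribosomal protein gene copy, differed by 0.96 ± 0.41 with overlapping groups. Under normexp background correction H2-Q7 differed by 0.098 and Rps4l by 0.043. That correction adds an offset of 50, which shrinks log2 differences of dim probes such as these. H2-Q7, Rps4l and the olfactory receptor genes have close paralogs, so the transcript behind their signal is uncertain. Lower averages in tMCAO were seen for Anxa8, an annexin, at -1.10, for Gabrg1, a GABA-A receptor subunit, at -0.86, for Apoe, the lipid carrier made mainly by astrocytes in brain, at -0.66, for Lhx1 at -0.88 and for Gamt, an enzyme of creatine synthesis, at -0.84. Each of these 5 overlapped between groups. Anxa8 and Lhx1 belong to a class of genes not expected in adult cortex, drawn up after the values were seen, so the transcript behind their signal is uncertain. Without sham 1 the differences were -0.70 for Anxa8, -0.50 for Gabrg1, -0.51 for Lhx1 and -0.47 for Gamt. Without sham 3 Lhx1 was at -1.54 and Gamt at -1.43. Over the alternatives in which each was tested, Anxa8 ranged from -1.75 to -0.43, Gabrg1 from -1.29 to -0.30, Apoe from -1.01 to -0.39, Lhx1 from -1.58 to -0.47 and Gamt from -1.43 to -0.46. For each of these 5 the value nearest 0 came with normexp background correction and quantile normalization.

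The differences were small for Actb, the cytoplasmic actin, at 0.05, for Gpi1, a glycolytic enzyme, at 0.15, and for Mbp, a myelin protein, at -0.03. The sign of Actb flipped to -0.05 under normexp background correction, and that of Mbp to 0.13 when scaled over probes detected on all 6 arrays. Of the 29 mRNA probes, 9 averaged higher and 20 lower in tMCAO. None passed an adjusted p of 0.05 in limma (0 probes, smallest adjusted p 0.356), and 2, Ppara and Rps4l, had an unadjusted p under 0.05. Without sham 3, 12 mRNA probes had an adjusted p under 0.05, with Ppara at 2.05 and an adjusted p of 1.58e-05, Anxa8 at -1.75 and Gabrg1 at -1.29 (limma). Ppara passed in 7 of its 23 alternatives, with adjusted p-values from 2.08e-09 to 0.774. In 5 of those 7, the fit without sham 3 and the smallest adjusted p included, every mRNA probe had 1 pooled SE, between 0.31 and 0.47, while the SD of Ppara in tMCAO was 1.55 with all 6 arrays. In the other 2, it passed without tMCAO 1 with an adjusted p of 0.000762 and with array row as a block at 0.0447 (limma).

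Of the 20 gene lists fixed before the data were examined, 4 had a member among the mRNA probes, with 1 gene each. Gabrg1, from the GABA list, differed by -0.86 with an adjusted p of 0.356 in limma. Mbp, from the oligodendrocyte list, differed by -0.03 with an adjusted p of 0.943. Kcnn2, a calcium-activated potassium channel, and Atg3, an autophagy enzyme, were not well above background on any array.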

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

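The form of this screen was chosen after the values had been seen. Corner marks, circRNA controls and normal controls were left out. Of 28 other control features (scanner controls, ERCC spike-ins and negatives) detected on at least 1 array, 4 were well above background on all tMCAO arrays, and for 1 of these, the spike-in control E1A_r60_a107, every tMCAO array lay above every sham array, by 1.17 on average (log2, scaled). It read -1.81, -0.97 and -0.99 on the tMCAO arrays and -2.67, -1.88 and -2.73 on the sham arrays. Chance gives 5% of features this order, or 0.2 of the 4. The screen looks for features higher in tMCAO alone. Of all 28, 19 averaged lower in tMCAO, among them ERCC-00168 at -1.44, ETG10_195139 at -1.40, ETG09_35454 at -1.27 and, detected on all 6 arrays, E1A_r60_3 at -0.93. ERCC-00168, ETG10_195139 and ETG09_35454 were well above background on 2 arrays only. For each of these and E1A_r60_3, sham 3 lay within or below the tMCAO values. Their differences came from sham 1 and sham 2, not from all sham arrays. Every tMCAO array lay above every sham array for 2 of the 28, whatever their detection, and below for 0. A narrower form of the screen, tried first, which asked for no detection on any sham array, picked 0 features.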

How the results depend on the processing

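Alternatives using array row, circRNA control probes, all non-control features, kept outlier spots or the mRNA probes were chosen after the data were seen. Of 23 alternatives, 2 gave circRNAs with an adjusted p under 0.05 in limma, where all 6 arrays equally weighted gave 0: array weights gave 223, with weights of 0.498, 0.635 and 2.19 for tMCAO 1 to 3 and 1.64, 2.98 and 0.294 for sham 1 to 3, and leaving out single arrays gave 0 to 112, the highest without sham 3. Of those 112, 111 were among the 223, all 111 with the same sign. Sham 3 had the lowest array weight, so these 2 fits make a similar change to the same arrays and their overlap is not separate support. The count at an unadjusted p under 0.05 and 1.5-fold, 77, became 40 with normexp background, 16 with normexp and quantile normalization, 131 with no filter, 312 with array weights, 18 with the plain test, 117 with array row as a block, 275 in row 1 alone, and 23 to 297 with 1 array left out, the lowest without sham 1 (26 without sham 2). With the replicate block it was 123, with 0 adjusted circRNA calls and 1 mRNA call; deviations of same-numbered samples correlated at -0.15, 0.46 and 0.18, and sham 1, sham 3 and tMCAO 1 did not correlate best with their own number (sham 3 and tMCAO 1 at 0.27 with each other, sham 1 at 0.24 with tMCAO 2). The median log2 difference moved to -0.067 with normexp, 0.18 when scaled over probes detected on all arrays and 0.10 with no filter, and lay between -0.01 and 0.07 with 1 array left out. mRNA probes with an adjusted p under 0.05 numbered 1 with normexp, 13 with array weights, 1 with array row as a block, 8 in row 1 alone, and 0 to 12 with 1 array left out. The counts with normexp, with array weights, in row 1 alone and without sham 3 (the 12) rest on fits that gave every mRNA probe 1 pooled SE. The difference in detected circRNAs was -139.2 to 38.3 with 1 array left out, reversed without tMCAO 3; that in brightness stayed below 0. Differences near 0 changed sign for Actb (-0.050 with normexp), for Mbp (0.13 when scaled over probes detected on all arrays, 0.30 with array weights, 0.022 in row 1 alone, and -0.18 to 0.16 with 1 array left out) and for Gpi1 (-0.091 to 0.31 with 1 array left out). Of 522 values for named probes, 475 kept their direction and side of the threshold, 39 newly passed it and 8 changed sign. The cause was not tested, except that fewer arrays or probes enter some of these fits. Blocks for slide or scan and all alternatives for host genes were not run. Signal over background limits the rest: 80.4% of circRNA probes were well above background on tMCAO 1 and 60.6% on tMCAO 3.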

Other observations

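All tests in this part were chosen after the results they bear on had been seen, and the gene classes used below were drawn up after the mRNA values were seen.

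Sham 3 lay nearer to the tMCAO arrays than to the other sham arrays. A wrong label on that array stays open and was not decided: in the fit without sham 3, the 100 circRNAs highest and the 100 lowest in tMCAO put it at a median of 1.03 on a scale from the other sham arrays at 0 to the tMCAO arrays at 1, but this restates the correlations between arrays and rests on 1 array. A difference in labelling or hybridisation stays open too. Of 28 control features, 15 were dimmer on sham 3 than on both other sham arrays (9.33 expected, one-sided binomial p = 0.0216, treating features as independent). Detection on at least 1 array was enough to enter. Features such as ETG10_195139 and ETG09_35454 were detected on 2 arrays only and were brightest on sham 1 and sham 2. Their entry favours a dimmer sham 3, so this count cannot decide. These are scaled values. tMCAO 1 was also below both other arrays of its group, at 21 of 28. It had the highest log2 75th percentile of its group subtracted, 7.37 against 6.43 and 6.17, which lowers its scaled values. Sham 3 had the lowest of the sham arrays subtracted, 6.67 against 7.09 and 7.01. The 21 therefore cannot show whether a dimmer sham 3 is particular to that array. Less linear mRNA left on sham 3 stays open. That explanation asks for a shift at least as low at abundant mRNAs as at genes not expected in cortex. The values ran the other way. The median shift of sham 3 from the other sham arrays (log2) was -0.05 at 6 abundant mRNAs and -1.35 at 8 genes not expected. Anxa8 and Lhx1 were among the 8. The difference was 1.31 (exact permutation p = 0.00666, with classes permuted over genes within 1 array, treating genes as independent). However, 4 of the 6 arrays reached p under 0.05 in this test (tMCAO 1 at 0.58, tMCAO 2 at -0.53, sham 2 at -0.65), so it cannot decide. The classes also overlapped, with Prdx2 at -1.15 and Apoe at -0.72 among the abundant and Spats1 at -0.42 and Duox1 at -0.52 among the others. Array row was not tested as an explanation. Sham 3 and tMCAO 3 were the only arrays in row 2, though sham 3 also correlated at 0.971 with tMCAO 1 in row 1. A biological difference between sham mice was not tested, and the label was kept as given throughout.

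The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For circRNAs with an adjusted p under 0.05, the real split gave 0 and the highest other 62. For the unadjusted rule with 1.5-fold, the real split gave 77 and the highest other 268, and 4 of 10 gave as many. For mRNA probes, the real split gave 0 and the highest other 14. With a real count of 0, every split gives as many, so the count of 10 splits says nothing for these 2 results. The highest split set tMCAO 1, tMCAO 3 and sham 3 against the rest. It was picked as the highest after all were seen. It places sham 3 with tMCAO 3 and tMCAO 1, the arrays it correlated with best. Whether the samples hold a structure beyond that resemblance was not tested.

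Ppara was highest on tMCAO 2, and 12 circRNAs correlated with it at r above 0.95 over the 6 arrays. Scaling of a dim array is argued against for Ppara itself, whose unscaled signal on tMCAO 2 was 2.45 (log2) above the brightest sham array. It stays open for the 12 circRNAs, which were picked for this profile: their unscaled signal on tMCAO 2 minus the brightest sham array was -0.25 to 2.21 (median 1.20) and exceeded the SD of their sham arrays for 8 of 12, while 3 had ranges below the 0.65 that scaling added to tMCAO 2 against sham 1, so that no excess before scaling was possible for them. Having 12 such partners is not particular to Ppara, because 57.3% of circRNAs with a range of at least 1 had as many. That share cannot tell chance from a pattern common to many probes, so chance similarity stays open for the circRNAs that share its profile. No biological explanation was tested.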
